A study of Mus musculus with 2 samples.

How the data were processed

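Polyadenylated RNA above 200 nucleotides from limb tissue of C57BL/6J embryos at embryonic day 14.5 was read as strand-specific paired ends of 101 nucleotides. Each of the 2 libraries is, per the labels, a pool of mixed-sex littermates and a separate biological replicate with 1 technical replicate. Both form the only group, so no comparison between conditions was made. Which limbs were taken and whether the pools came from separate litters is not given in the labels.

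For each library the authors deposited a gene table and a transcript table made against mm10 with GENCODE M4 annotation, per the text file deposited with the tables. The program that made the tables is not given in the sources used here. The tables give, per the file headers, the expected count of each gene, that is the estimated number of reads after sharing reads that fit several genes. They also give, per the file headers, TPM and posterior mean TPM. In the transcript tables the share of each transcript in its gene is given in percent, per the file headers. These deposited values were used as they stand, without realignment. The read files and signal tracks were not used here.

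Gene names, biotypes and coordinates came from GENCODE M21 (GRCm38, the same assembly as mm10), joined by stable gene identifier. Of 43346 gene rows in the tables, 884 had no match in M21 and kept their identifier. Expected counts of 3014 genes were, as deposited, more than 0.005 from a whole number in either library, the sign of reads shared with other genes. A whole count does not exclude shared reads. The ERCC spike-in, phiX and tRNA rows were left out of library sizes and tests. The ERCC rows took 2.39% and 2.36%, and the phiX row 1.35% and 1.94%, of all deposited counts in replicates 1 and 2.

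Without these rows the libraries held 110172148 and 103363136 deposited counts. A count of 0 was read as up to 3 counts. TMM factors from edgeR were 1.01 and 0.992, and the DESeq2 size factors used as an alternative were 1.04 and 0.961. A gene was called detected at a deposited TPM of at least 1 in both libraries. Correlation used log2(TPM + 1) of the deposited TPM across all genes. Spread between the libraries was the absolute log2 ratio of deposited TPM among genes with a mean of at least 10. The common dispersion came from an intercept-only edgeR model over the 20396 genes with at least 10 counts in total. Shares of counts were given with 95% Wilson intervals.

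Counts of the libraries were compared gene by gene with an exact two-sided conditional binomial test on rounded deposited expected counts, with the TMM-scaled library sizes as the null share and Benjamini-Hochberg adjustment at 0.05. This test compares those libraries, not the conditions. Ratios were stabilised with a prior count of 0.5. Genes were contrasted within the tissue by an intercept-only limma fit to log2(TPM + 1) of the deposited TPM, with eBayes and a trend, over genes with a mean of at least 1 TPM or named in a contrast. The difference of a pair used the moderated variances of both genes, and p was adjusted over the 40 pairs.

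The lists were chondrocyte, hypertrophic cartilage, osteoblast, osteoclast, joint interzone, tendon, extracellular matrix fibroblast, myogenic regulator, embryonic sarcomere, adult fast muscle, epidermis, cornified epidermis, apical ectodermal ridge, limb mesenchyme transcription factors, limb identity, the Hoxa, Hoxb, Hoxc and Hoxd clusters, and hedgehog, BMP and GDF, FGF, Wnt and retinoic acid signalling. Further lists were interdigit cell death, endothelium, pericyte and smooth muscle, erythroid, macrophage, other blood lineages, Schwann cell, melanoblast, neuron, adipocyte, liver, heart, lung with gut, kidney and pancreas, forebrain and spinal cord, proliferation, imprinted, immediate early and heat shock, hypoxia and glycolysis, and sex-linked transcripts. The median level of each list was ranked among 10000 random lists of protein-coding genes of the same size. The median log2 ratio of members with a mean of at least 1 TPM was ranked among 10000 random lists drawn, for each member, from the 50 genes on either side in mean expression. A list stood apart beyond the outermost 0.5% of random lists on either side with at least 5 members. The erythroid gene Ahsp had no row under its name and was left out.

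The lists, the pairs, the isoform genes, the tests and most of their variations were chosen before the data were examined, as was the rule for naming genes. By that rule the text names the 10 highest nuclear genes, the mitochondrial genes as a group, and the 4 highest members of each list with members under 1 TPM in both libraries where a list has 5 or fewer of them. It also names the genes of each pair, sex-linked transcripts, isoform genes, all Hox members, and per direction the 10 largest library ratios among genes with a mean of at least 10 TPM and an adjusted binomial p under 0.05. Any other gene is marked as chosen after its values were seen. Some results on single genes are not reported here.

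The tests were varied with other detection limits, other scalings (DESeq2 size factors, total counts, spike-ins), other pseudocounts, deposited posterior mean TPM, CPM (counts scaled by library size alone), an edgeR exact test with the common dispersion, a fit without trend or without the low-value filter, other list filters and each library alone. Removal of the GC and length trend (LOWESS, fraction 0.3, over 14850 genes with at least 50 counts), restriction to whole counts and a protein-coding subset were added after seeing the data. Isoform agreement covered genes with several transcripts and at least 10 TPM in both libraries.

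The steps were tested on simulated data. Among 23889 simulated genes the binomial step called 78 of 100 genes changed 1.2-fold and 100 of 100 changed 2-fold, and 9 of 23689 unchanged genes. The list step found 50 of 50 lists shifted by 0.5 log2 and placed 4 of 200 unshifted lists outside the limits. Simulated counts held counting noise alone, and simulated list values were independent, with a spread below the SD of 0.44 of the real log2 ratios. The real libraries differed by far more than counting noise (chi-square of 107 per degree of freedom) and held a GC trend. False calls in the real data can therefore be more frequent than in these simulations. The 95% limma intervals held the true difference for 38 of 40 pairs. Computation used R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.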

Results

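Polyadenylated RNA longer than 200 nucleotides was sequenced from limb tissue of C57BL/6J mouse embryos at embryonic day 14.5, when cartilage, tendon, muscle and skin are forming in the limb. The samples form 1 group of 2 biological replicates, each a pool of male and female littermates, so no conditions can be compared. What the design allows is the level of each gene in the tissue, the contrast of chosen genes within it, and the difference between the 2 libraries. Both replicates carry the same donor identifier and separate biosample identifiers. Because the labels do not say whether the pools came from separate litters, p-values measure only the spread between these 2 samples, which may be partly technical. The labels also do not say whether forelimbs, hindlimbs or both were taken.

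Gene rows summed to 110172148 estimated counts in replicate 1 and 103363136 in replicate 2. At this depth a count of 0 allows up to 3 counts, or 0.0272 and 0.0290 CPM (counts scaled by library size alone) in replicates 1 and 2. The widest 95% Wilson interval of any share of counts given here reached 0.00743 percentage points to either side; such intervals and floors cover counting error only. Spike-in RNAs of the ERCC set took 2.39% and 2.36% of all counts, and the 74 of 96 spike-ins with counts in both libraries had a Pearson correlation of 0.993 between their log2 counts.

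Transcripts of 14663 genes reached 1 TPM (abundance scaled by transcript length and library size) in both libraries, among them 13494 of the 21474 protein-coding genes in the table. Across all genes, which are not independent replicates, log2(TPM + 1) of the 2 libraries correlated with a Pearson r of 0.994 and a Spearman rho of 0.964. Of the 9623 genes with a mean of at least 10 TPM, 98.5% lay within 2-fold of each other in the 2 libraries. Their median absolute log2 ratio was 0.21, or 1.16-fold. Against counting noise alone the counts of the libraries gave a chi-square of 107 per degree of freedom over 24394 genes.

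The most abundant nuclear transcripts were long noncoding RNAs, globins and parts of the translation machinery. In first place was Gm42418 (ENSMUSG00000098178.1, chromosome 17, 39846958 to 39848788), annotated as a long intergenic noncoding RNA, at 11323 ± 176 TPM (SD, n = 2). The imprinted noncoding RNAs Meg3 at 8985 ± 1473 TPM, H19 at 8521 ± 550 TPM and Rian at 5715 ± 971 TPM (SD, n = 2) belonged to the same top 10. Adult haemoglobin chains contributed Hba-a2 at 8284 ± 573 TPM and Hbb-bs at 6366 ± 514 TPM, and translation was represented by Rplp1, Eef1a1 and Rps12 at 7913 ± 680, 6880 ± 1006 and 6369 ± 41.5 TPM (SD, n = 2). Rn7sk, the noncoding regulator of transcription elongation, stood at 6365 ± 1329 TPM (SD, n = 2). Its TPM was 5426 and 7304 in replicates 1 and 2, with 54002 and 54010 counts. Its effective length was short, at 133 and 106 nucleotides in replicates 1 and 2, so its level and SD also hold that difference in length. Of these 10 genes, Gm42418, H19 and Rian held only whole counts, which does not exclude shared reads. The others shared part of their reads with other genes, so their levels are less certain. H19 is uncertain as well: its counts fell from 1194804 to 919827 in replicate 2 while its TPM rose from 8132 to 8910. Its effective length was 1959 and 1479 nucleotides in replicates 1 and 2.

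Ribosomal protein genes took 4.09% ± 0.766 of the counts, mitochondrial genes 1.53% ± 0.122 and haemoglobin genes 0.592% ± 0.0218 (SD, n = 2). The 10 genes with the most counts held 6.12% ± 0.0366 of them (SD, n = 2), so no small set of genes dominated either library. In TPM the mitochondrial share was 6.94%, of which the single short gene mt-Atp8 made up 4.06 percentage points: its effective length was 13.9 and 7.49 nucleotides in the 2 tables, which inflates a value scaled by length. Without mt-Atp8 the mitochondrial share of TPM was 2.88%. Protein-coding genes took 94.4% ± 0.0479 of the counts and long intergenic noncoding RNAs 3.63% ± 0.0992 (SD, n = 2).

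To describe which tissues and pathways the RNA represents, 43 gene lists were fixed before the data were examined and 40 pairs of genes were compared within the tissue. Of the pairs, 29 differed beyond the replicate spread (limma on log2(TPM + 1), Benjamini-Hochberg adjusted over the 40 pairs), and all 29 had the same sign in both libraries. Without the filter on low values, limma called 0 of the 40 pairs (18 at an unadjusted p under 0.05), with 1.68 in place of 5.37 moderated degrees of freedom. Each of the 29 calls therefore rests on that filter. In CPM, with no length scaling, 33 pairs passed. Several called log2 differences changed greatly in size: Scx over Mkx became 0.64, Gli3 over Gli1 -0.59 and Igf2 over Igf2r 3.39. Among the others Fgf10 over Fgf8 became 3.62, Sox10 over Tubb3 1.52, Igf2 over Igf1 5.00, Col2a1 over Col10a1 4.05 and Hba-a1 over Hba-x 4.96. A CPM difference between 2 genes also holds the difference in their transcript lengths. Calls gained or lost in CPM therefore do not decide whether the levels of 2 genes differ. Folds given for pairs are on the log2(TPM + 1) scale, which shrinks the fold of a gene near 1 TPM or below. The SE treats the genes of a pair as measured apart although they share libraries, and 38 of the 40 pairs had the same sign in both libraries, including pairs that did not pass. List medians are medians of the members' mean TPM, except where the mean of the library medians is given with its SD. Of the 43 lists, 9 had a median level above the 99th percentile of 10000 random lists of protein-coding genes of the same size. That reference includes genes that were not detected. Against protein-coding genes with a mean of at least 1 TPM, basal and suprabasal epidermis fell to percentile 88.4. Limb mesenchyme transcription factors fell to 83.9, and hypoxia and glycolysis genes to 95.1.

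Cartilage genes were among the strongest signals of the tissue. All 20 members of the chondrocyte list exceeded 1 TPM in both libraries, with library medians averaging 164 ± 12 TPM (SD, n = 2), and 12 of them exceeded 100 TPM in both. Col2a1 (ENSMUSG00000022483.12, chromosome 15, 97975602 to 98004695), the main fibrillar collagen of cartilage, reached 1496 ± 179 TPM. Next came Col9a3 at 528 ± 20.9, Matn1 at 426 ± 49.2 and Matn4 at 353 ± 73.3 TPM (SD, n = 2), which encode other proteins of the cartilage matrix. Genes of maturing, hypertrophic cartilage were also present, 10 of 10 above 1 TPM with a median of 32.1 TPM, led by Pth1r, the receptor of parathyroid hormone-related protein, at 146 ± 30.2 TPM and by Col10a1, the collagen of hypertrophic chondrocytes, at 140 ± 4.07 TPM (SD, n = 2). Col2a1 nevertheless stood 10.6-fold above Col10a1 (log2 difference 3.40, SE 0.24, adjusted p = 6.34e-05, limma).

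Osteoblast genes were mostly detected, with markers of later bone low. Of 15 osteoblast genes 12 were detected, with library medians averaging 15.7 ± 1.04 TPM (SD, n = 2). Col1a1 and Col1a2, which many mesenchymal cells also express, led at 1232 ± 71.9 and 1088 ± 17.8 TPM, and Ibsp, a bone matrix protein gene shared with the hypertrophic list, followed at 85.5 ± 29.9 TPM (SD, n = 2). The osteoblast transcription factors Runx2 and Sp7 stood at 26.8 ± 5.56 and 22.4 ± 5.70 TPM, and their difference did not pass the test (log2 difference 0.25, SE 0.22, adjusted p = 0.338, limma). In CPM it did (log2 difference 0.91, adjusted p = 0.00339, limma). Markers of later bone stayed low: Bglap, the osteocalcin gene, had 0.805 ± 0.0212 TPM, Bglap2 0.465 ± 0.0495 and Sost, expressed by osteocytes, 0.705 ± 0.0495 TPM (SD, n = 2). Sp7 was 12.8-fold above Bglap on the log2(TPM + 1) scale and 27.8-fold by mean TPM (log2 difference 3.67, SE 0.21, adjusted p = 3.12e-05, limma); Bglap and Bglap2 share reads and are uncertain. Sox9, the regulator of chondrogenesis, exceeded Runx2 by 2.68-fold (log2 difference 1.42, SE 0.24, adjusted p = 0.00284, limma). Osteoclast genes were detected for 6 of 11 members with a median of 1.66 TPM; Ctsk, the collagen-degrading cathepsin, was 2.71-fold above Acp5 (log2 difference 1.44, SE 0.19, adjusted p = 0.000987, limma), whereas Calcr, the calcitonin receptor gene, had 0.245 ± 0.00707 TPM (SD, n = 2).

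Connective tissue lineages were well represented. All 13 tendon genes were detected with library medians averaging 66.8 ± 3.41 TPM (SD, n = 2), from Dcn at 368 ± 49.8 and Col12a1 at 261 ± 20.7 TPM to Kera at 116 ± 1.43 TPM and the tendon transcription factor Scx at 113.8 ± 31.8 TPM (SD, n = 2). Scx exceeded Mkx, another tendon regulator, by 3.31-fold (log2 difference 1.73, SE 0.27, adjusted p = 0.00207, limma). Extracellular matrix genes of fibroblasts had a median of 250.0 TPM (14 of 14 detected), with Col3a1 at 1084 ± 252, Fn1 at 521 ± 0.269, Postn at 479 ± 138 and Lum at 401 ± 1.51 TPM (SD, n = 2). Joint interzone genes were detected for 12 of 12 members with a median of 22.5 TPM, among them Sfrp2 at 452 ± 116 and Gdf5, a marker of forming joints, at 41.0 ± 9.91 TPM (SD, n = 2). Gdf5 was above Prg4, the lubricin gene of later joint surfaces, by 14.8-fold on the log2(TPM + 1) scale and 22.8-fold by mean TPM (log2 difference 3.89, SE 0.21, adjusted p = 3.12e-05, limma). Col1a1 and Col2a1 did not differ beyond the replicate spread (log2 difference of Col2a1 over Col1a1 0.28, 95% interval -0.38 to 0.93, adjusted p = 0.370, limma). Neither did Col1a1 and Col3a1, whose order differed between the libraries (log2 difference 0.20, 95% interval -0.48 to 0.88, adjusted p = 0.497, limma).

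Embryonic sarcomere genes, which encode the contractile apparatus of developing muscle, were abundant. All 20 embryonic sarcomere genes were detected with library medians averaging 115 ± 41.4 TPM (SD, n = 2), led by Actc1, the cardiac actin that embryonic skeletal muscle also uses, at 1132 ± 21.1 TPM, Mylpf at 685 ± 328, Acta1 at 670 ± 22.9 and Tnnc1 at 314 ± 95.3 TPM (SD, n = 2). Actc1 exceeded Acta1 by 1.69-fold (log2 difference 0.76, SE 0.24, adjusted p = 0.0342, limma). The embryonic myosin heavy chain Myh3 exceeded the perinatal Myh8 by 4.86-fold (log2 difference 2.28, SE 0.31, adjusted p = 0.00115, limma) and the slow Myh7 by 6.70-fold (log2 difference 2.74, SE 0.28, adjusted p = 0.000344, limma). The adult fast myosins had means below 1 TPM, with Myh1 at 0.75 ± 0.198, Myh2 at 0.110 ± 0.0283 and Myh4 at 0.0850 ± 0.00707 TPM (SD, n = 2). Of the 10 adult fast muscle genes 5 were detected, led by Ckm at 69.7 ± 20.8 TPM (SD, n = 2). Of 16 myogenic progenitor and regulator genes 15 were detected with a median of 8.11 TPM. Myog, which drives differentiation, exceeded Myod1 (log2 difference of Myod1 over Myog -0.77, SE 0.22, adjusted p = 0.0220, limma), a call lost in CPM (adjusted p = 0.0569, limma). Pax7 exceeded Pax3, the earlier progenitor marker, by 3.80-fold on the log2(TPM + 1) scale and 9.41-fold by mean TPM (log2 difference 1.92, SE 0.20, adjusted p = 0.000357, limma), and Pax3 itself had 0.510 ± 0.0849 TPM (SD, n = 2). The troponins Tnnt3 and Tnnt1 did not pass (log2 difference -1.19, SE 0.47, adjusted p = 0.0643, limma), except in CPM (log2 difference -1.11, adjusted p = 0.0260, limma).

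Genes of basal and suprabasal epidermis were abundant, and those of cornified epidermis were low. All 17 basal and suprabasal epidermal genes were detected with library medians averaging 31.2 ± 12.1 TPM (SD, n = 2). The basal keratins Krt5 and Krt14 stood at 285 ± 68.3 and 219 ± 34.8 TPM, Krtdap of differentiating keratinocytes at 252 ± 18.5 and the suprabasal Krt1 at 155 ± 52.3 TPM (SD, n = 2). Krt14 exceeded Krt8, a keratin of simple epithelium and periderm, by 36.9-fold (log2 difference 5.21, SE 0.28, adjusted p = 3.12e-05, limma). Krt5 exceeded the suprabasal Krt10 by 1.93-fold (log2 difference 0.95, SE 0.31, adjusted p = 0.0342, limma), and Krt10 exceeded Lor, a protein of the cornified envelope, by 16.7-fold (log2 difference 4.07, SE 0.27, adjusted p = 6.17e-05, limma). Of 9 cornified epidermis genes 3 were detected, Lor at 7.71 ± 0.509, Tgm3 at 3.48 ± 0.919 and Casp14 at 2.04 ± 0.75 TPM (SD, n = 2). Flg, the filaggrin gene, chosen after its values were seen, had 0 counts in both libraries, which allows up to 0.0272 and 0.0290 CPM. Apical ectodermal ridge genes, which mark the growing tip of the limb bud, were low: 10 of 13 were detected with a median of 4.85 TPM, and Fgf4 and Fgf17 had 0.510 ± 0.0566 and 0.480 ± 0.0283 TPM (SD, n = 2). Mesenchymal Fgf10 exceeded ridge Fgf8 by 3.65-fold on the log2(TPM + 1) scale and 6.10-fold by mean TPM (log2 difference 1.87, SE 0.17, adjusted p = 0.000222, limma).

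**Figure D1:**
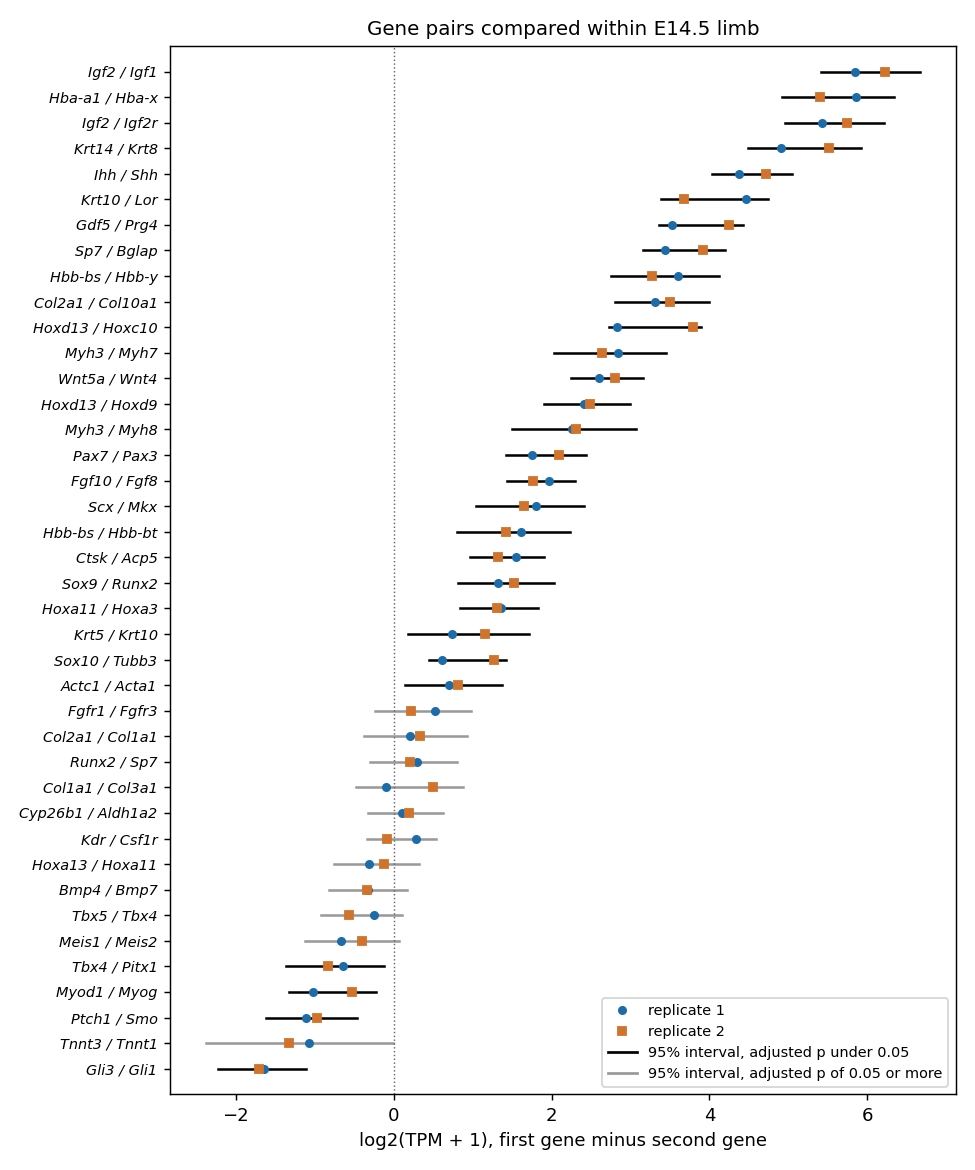
Difference of log2(TPM + 1) between the genes of each of the 40 pairs compared within limb tissue (horizontal axis, first gene minus second gene), with each library as a point and the 95% limma interval as a line. The 29 pairs with an adjusted p under 0.05 are drawn in black, and they range from Gli3 below Gli1 at -1.67 to Igf2 above Igf1 at 6.04.

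Hox genes encode transcription factors of body and limb position, and the highest members belonged to the Hoxa and Hoxd clusters. In the Hoxd cluster, whose last paralogues act in digit formation, Hoxd13 (ENSMUSG00000001819.4, chromosome 2, 74668310 to 74671599) had 107 ± 22.4 TPM, Hoxd12 41.8 ± 8.19, Hoxd11 41.5 ± 11.6 and Hoxd10 31.9 ± 1.29 TPM (SD, n = 2), while Hoxd3 and Hoxd1 had 2.06 ± 0.304 and 0.450 ± 0.0566 TPM. In the Hoxa cluster Hoxa10 and Hoxa9 led at 102 ± 13.8 and 99.7 ± 14.7 TPM, above Hoxa11 at 30.4 ± 4.70 and Hoxa13 at 26.2 ± 6.51 TPM (SD, n = 2). Hoxb genes peaked at 8.0 ± 0.0778 TPM for Hoxb2, and Hoxc genes at 9.91 ± 2.77 TPM for Hoxc10 (SD, n = 2). Detected members numbered 11 of 11 for Hoxa, 8 of 10 for Hoxb, 9 of 9 for Hoxc and 8 of 9 for Hoxd. Hoxd13 exceeded Hoxd9 by 5.46-fold (log2 difference 2.45, SE 0.22, adjusted p = 0.000188, limma) and Hoxc10 by 9.92-fold (log2 difference 3.31, SE 0.23, adjusted p = 6.34e-05, limma). Hoxa11 exceeded Hoxa3 by 2.52-fold (log2 difference 1.33, SE 0.20, adjusted p = 0.00154, limma). Hoxa13 and Hoxa11, markers of the hand or foot plate and the zone next to it, did not differ beyond the spread (log2 difference -0.22, 95% interval -0.76 to 0.32, adjusted p = 0.374, limma), but in CPM Hoxa13 was lower (log2 difference -0.47, adjusted p = 0.0391, limma).

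**Figure D2:**
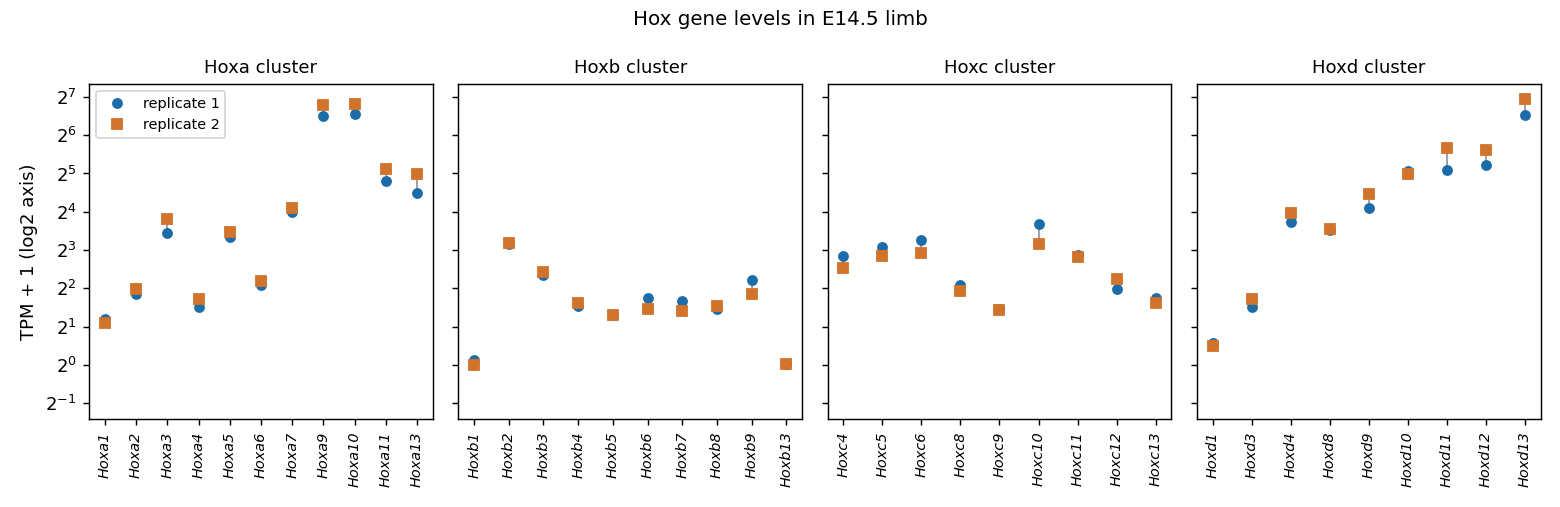
Level of every Hox gene in the 2 limb libraries as TPM + 1 on a log2 axis, 1 panel per cluster with genes ordered by paralogue number and a line joining the replicates. Hoxd13 at 107 TPM and Hoxa10 at 102 TPM are the highest members of their clusters, and all Hoxb and Hoxc means lie below 10 TPM.

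Genes of forelimb and of hindlimb identity were all detected. The forelimb factor Tbx5 stood at 27.5 ± 2.02 TPM and the hindlimb factors Tbx4 and Pitx1 at 37.2 ± 8.39 and 63.4 ± 19.8 TPM (SD, n = 2). In replicates 1 and 2, Tbx5 had 26.1 and 28.9 TPM and Tbx4 31.2 and 43.1 TPM. Pitx1 had 49.5 and 77.4 TPM. Each pool therefore held transcripts of factors of both limbs, although the labels do not say which limbs were taken. Tbx5 and Tbx4 did not differ beyond the replicate spread (log2 difference -0.41, 95% interval -0.91 to 0.10, adjusted p = 0.121, limma). Tbx4 was below Pitx1 (log2 difference -0.74, SE 0.25, adjusted p = 0.0386, limma), a call lost in CPM (adjusted p = 0.291, limma). All 9 members of this list were detected with a median of 6.84 TPM. Limb mesenchyme transcription factors were detected for 19 of 19 members with library medians averaging 28.8 ± 4.48 TPM (SD, n = 2), led by Twist1 at 248 ± 44.7, Twist2 at 237 ± 53.5, Prrx2 at 183 ± 51.1 and Prrx1 at 100.985 ± 0.615 TPM (SD, n = 2). Meis1 and Meis2, which mark the proximal limb, stood at 11.7 ± 2.52 and 17.6 ± 6.04 TPM; their difference missed the threshold (log2 difference -0.53, adjusted p = 0.0920, limma) and passed it with posterior mean TPM (log2 difference -0.65, adjusted p = 0.0406, limma).

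Genes of the hedgehog, BMP, FGF, Wnt and retinoic acid pathways, which act in limb growth and patterning, were mostly detected. Among hedgehog genes, 12 of 13 detected with a median of 29.6 TPM, the cartilage ligand Ihh exceeded Shh, the ligand of the early limb bud, by 23.3-fold on the log2(TPM + 1) scale and 98.5-fold by mean TPM (log2 difference 4.54, SE 0.20, adjusted p = 2.27e-05, limma); Shh had 0.30 ± 0.0283 TPM (SD, n = 2). Gli1, a target of the pathway, exceeded the repressor-forming Gli3 (log2 difference of Gli3 over Gli1 -1.67, SE 0.22, adjusted p = 0.00107, limma). Ptch1 lay below Smo in TPM (log2 difference -1.04, SE 0.23, adjusted p = 0.00827, limma) but not in CPM (log2 difference -0.18, adjusted p = 0.436, limma). BMP and GDF genes (17 of 17 detected, median 27.4 TPM) were led by the BMP targets Id1 at 416 ± 65.6 and Id3 at 403 ± 79.0 TPM, FGF genes (15 of 16, median 27.8 TPM) by the receptors Fgfr1 at 156 ± 19.8 and Fgfr3 at 122 ± 33.5 TPM, and Wnt genes (17 of 17, median 21.8 TPM) by the modulator Sfrp2, followed by Wnt11 at 117 ± 34.3 and Wnt5a at 89.9 ± 5.84 TPM (SD, n = 2). Wnt5a exceeded Wnt4 by 6.53-fold (log2 difference 2.71, SE 0.18, adjusted p = 6.17e-05, limma). Bmp4 and Bmp7, and Fgfr1 and Fgfr3, did not pass in TPM (log2 differences -0.32 and 0.37, adjusted p = 0.184 and 0.209, limma) and passed in CPM (log2 differences -1.54 and 0.70, adjusted p = 5.96e-05 and 0.0115, limma). Retinoic acid genes were detected for 12 of 14 members with a median of 16.4 TPM, led by the binding protein gene Crabp1 at 592 ± 104 TPM (SD, n = 2). The degrading enzyme Cyp26b1 and the synthesising Aldh1a2 did not differ in TPM (log2 difference 0.15, adjusted p = 0.480, limma), but Cyp26b1 was higher in CPM (log2 difference 1.25, adjusted p = 0.000300, limma). Interdigit cell death genes were detected for 10 of 10 members with a median of 21.8 TPM, Bax leading at 95.8 ± 13.9 TPM (SD, n = 2).

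Genes of vessels, blood cells, nerve-associated cells and pigment cells were detected at varied levels. Endothelial genes were detected for 14 of 14 members with a median of 28.8 TPM, led by Egfl7 at 236 ± 25.3 TPM, and pericyte and smooth muscle genes for 8 of 9 with a median of 22.4 TPM, led by Acta2 at 275 ± 2.43 TPM (SD, n = 2). Macrophage genes (15 of 15, median 15.1 TPM) were led by Tyrobp and C1qb at 50.9 ± 12.4 and 50.5 ± 5.27 TPM (SD, n = 2). The endothelial receptor Kdr and the macrophage receptor Csf1r did not differ in TPM (log2 difference 0.10, 95% interval -0.34 to 0.53, adjusted p = 0.595, limma), and Kdr was higher in CPM (log2 difference 0.69, adjusted p = 0.00614, limma). Erythroid genes were detected for 13 of 16 members, with adult globins far above embryonic ones. Hba-a1 exceeded the embryonic Hba-x by 49.5-fold (log2 difference 5.63, SE 0.28, adjusted p = 3.03e-05, limma) and Hbb-bs exceeded the embryonic Hbb-y by 10.8-fold (log2 difference 3.44, SE 0.27, adjusted p = 0.000108, limma). Hbb-bs also exceeded Hbb-bt (log2 difference 1.52, SE 0.28, adjusted p = 0.00423, limma), but these near-identical copies share reads, as do Hba-a1 and Hba-a2. Other blood lineages (7 of 12 detected, median 3.88 TPM) were led by Cpa3 of mast cells at 62.6 ± 8.46 TPM and Pf4 of platelets at 37.0 ± 5.26 TPM (SD, n = 2), while the T cell gene Cd3e and the B cell gene Ms4a1 lay at or below 0.0700 TPM. Schwann cell genes were detected for 10 of 11 members (median 14.2 TPM), melanoblast genes for 5 of 8 (median 2.40 TPM), adipocyte genes for 3 of 9 (median 0.270 TPM) and neuron genes for 7 of 12 (median 2.03 TPM). Sox10 of Schwann cells exceeded the neuronal Tubb3 by 1.92-fold (log2 difference 0.94, SE 0.19, adjusted p = 0.00629, limma).

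Cell cycle and fetal growth genes were abundant. All 18 proliferation genes were detected with library medians averaging 86.9 ± 4.98 TPM (SD, n = 2), led by the mitotic kinase Cdk1 at 293 ± 27.4 and the replication clamp Pcna at 247 ± 21 TPM. Imprinted genes formed the strongest list, 16 of 16 detected with library medians averaging 632 ± 19.7 TPM (SD, n = 2), and the fetal growth factor Igf2 at 3964 ± 639 TPM (SD, n = 2) exceeded Igf1 by 65.7-fold (log2 difference 6.04, SE 0.25, adjusted p = 2.27e-05, limma) and its clearance receptor Igf2r by 48.0-fold (log2 difference 5.58, SE 0.25, adjusted p = 2.27e-05, limma). Hypoxia and glycolysis genes (12 of 12, median 42.2 TPM) were led by the glycolytic Ldha at 587 ± 18.7 and Aldoa at 501 ± 29.0 TPM (SD, n = 2). Immediate early and heat shock genes, which respond to handling and stress, were detected for 11 of 12 members with a median of 18.9 TPM, Hsp90aa1 leading at 137 ± 4.84 and Jun following at 64.5 ± 14.6 TPM (SD, n = 2).

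Lists of other organs held fewer detected members than most limb lists, with some genes at moderate levels. None of the 10 genes for lung, gut, kidney and pancreas epithelium reached 1 TPM in either library, and the highest of them, the brush border gene Vil1, had 0.360 ± 0.339 TPM (SD, n = 2). Heart genes were detected for 3 of 9 members, led by Myl2, which slow skeletal muscle also uses, at 11.3 ± 4.52 TPM, and forebrain and spinal cord genes for 3 of 10, led by Emx2 at 15.6 ± 2.04 TPM (SD, n = 2). Liver genes were detected for 6 of 10 members with a median of 4.33 TPM, with Afp at 21.6 ± 2.82 and the transferrin gene Trf at 15.3 ± 1.39 TPM (SD, n = 2).

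Between the 2 libraries, muscle contraction, epidermis and Y-linked transcripts were lower in replicate 2, and limb mesenchyme transcription factors and BMP and GDF genes were higher. Chondrocyte, Hoxd, hedgehog, FGF and Wnt genes were also higher, but no longer stood apart once a GC and length trend between the libraries was removed. With counts scaled by TMM, the exact binomial test called 12151 of 24394 genes different after Benjamini-Hochberg adjustment, 6089 higher and 6062 lower in replicate 2. It compares those libraries, not the conditions, and at this depth it calls small differences: 386 genes were higher and 835 lower by at least 2-fold. With the replicate spread included through the common dispersion (biological coefficient of variation 0.195), edgeR's exact test called 203 genes, 54 higher and 149 lower. That dispersion was estimated from the same 2 libraries, so the 203 genes are those that differ most relative to the typical gene, not an independent test. Genes rich in GC were counted more often in replicate 2, with a median log2 ratio of -0.17 in the lowest and 0.24 in the highest quintile of GC content and a Spearman rho of 0.46 across 14850 genes, which are not independent replicates. By transcript length the median ran from -0.12 in the shortest to 0.06 in the longest quintile.

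Many of the largest ratios fell on small RNAs, pseudogenes and duplicated genes whose reads are hard to place. Among the 10 genes highest in replicate 2 by the fixed rule were the small nucleolar RNAs Rnu3b4 and Rnu3b2. Both had 0 and 21 counts in replicates 1 and 2 and equal TPM. Their reads may be shared too, although these counts were whole. The related Rnu3b1 and Rnu3b3 each had 58.5 and 0 counts and shared reads with other genes. Srp54a, a gene of the signal recognition particle, had 2268 counts in replicate 1 and 0 in replicate 2, and it shares reads with other genes. Among the same extremes, Gm21887 on the X chromosome (ENSMUSG00000095562.3, 170009659 to 170019281) rose from 9300 to 42332 counts, and Gm21887 and Eif2s3y held only whole counts, whereas part of the Xist reads was shared. Gm22513, Snhg9, Gm27627, Gm27000, Rps27rt and Hist2h2aa2 completed the genes higher in replicate 2. Pseudogenes made up most of the other side, with Gm15452, Gm14567, Gm10132, Llph-ps2, Gm12338 and Gm7206 lower in replicate 2.

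Of the 43 lists, 11 stood apart from 10000 random lists matched on expression, 8 higher and 3 lower in replicate 2. Hedgehog genes had a median log2 ratio of 0.36, with 10 of 12 compared members higher and 1 lower by the binomial test, such as Ptch1 at 0.57 and Gli1 at 0.44. Limb mesenchyme transcription factors had a median of 0.28 (14 of 19 higher, 2 lower), Prrx2 leading its abundant members at 0.62. Chondrocyte genes had a median of 0.23 (14 of 20 higher, 6 lower), with Sox9 at 0.63 and Matn4 at 0.42. In the Hoxd cluster the median was 0.38 (5 of 8 higher, 1 lower), and Hoxd13 had 0.43. BMP and GDF genes had a median of 0.24 (12 of 17 higher, 3 lower), FGF genes 0.28 (10 of 16 higher, 2 lower) and Wnt genes 0.23 (11 of 17 higher, 2 lower), with Id3 at 0.39, Fgfr3 at 0.43 and Wnt11 at 0.47. Other blood lineages had a median of 0.37 (6 of 8 higher, 2 lower), among them S100a8 of granulocytes at 0.82. Adjusted over the list alone, the counts were 6 higher and 1 lower for Hoxd, 12 and 4 for BMP and GDF, and 12 and 2 for Wnt genes, and did not differ for the other lists that stood apart.

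Removing the GC and length trend, a step chosen after seeing the data, took 5 of these 8 lists back inside the range of the random lists. The medians became 0.08 for chondrocyte, 0.11 for hedgehog, 0.08 for Hoxd, 0.15 for FGF and 0.09 for Wnt genes. Limb mesenchyme transcription factors kept a median of 0.19, BMP and GDF genes 0.20 and other blood lineages 0.36, still above the upper limit of the random lists. Ratios of the deposited TPM in place of counts took the chondrocyte, Hoxd, Wnt and other blood lists inside the limits (medians 0.26, 0.34, 0.23 and 0.19), as did restricting other blood lineages to members of at least 5 TPM (median 0.16) and Hoxd to members with whole counts (median 0.36).

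Sarcomere genes were lower in replicate 2 by a median log2 ratio of -0.65, or 1.57-fold, with 17 of 20 lower, 2 higher and 1 neither by the binomial test. The fast and slow troponins Tnnt3 and Tnnt1 had log2 ratios of -1.60 and -1.28 and Mylpf, the fast regulatory light chain, -1.04, while Actc1 differed by 0.02 and Acta1 by -0.09. Regulators of myogenesis did not share this: their list had a median of 0.19, within the limits, with 9 of 15 higher and 3 lower, Myod1 at 0.43 and Myog at -0.07, and the median was 0.08 with the GC and length trend removed. Epidermal genes were lower by a median of -0.45, or 1.36-fold, with 16 of 17 lower and 0 higher. Krt10 had a log2 ratio of -0.92, Krt1 -0.71 and Krt5 -0.50, whereas Trp63, the transcription factor of the basal layer, had 0.00 and did not pass. For both lists the counts adjusted over the list alone were the same. With the GC and length trend removed the medians were -0.54 for sarcomere and -0.52 for epidermal genes, below all 10000 random lists, as were the main values.

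**Figure D3:**
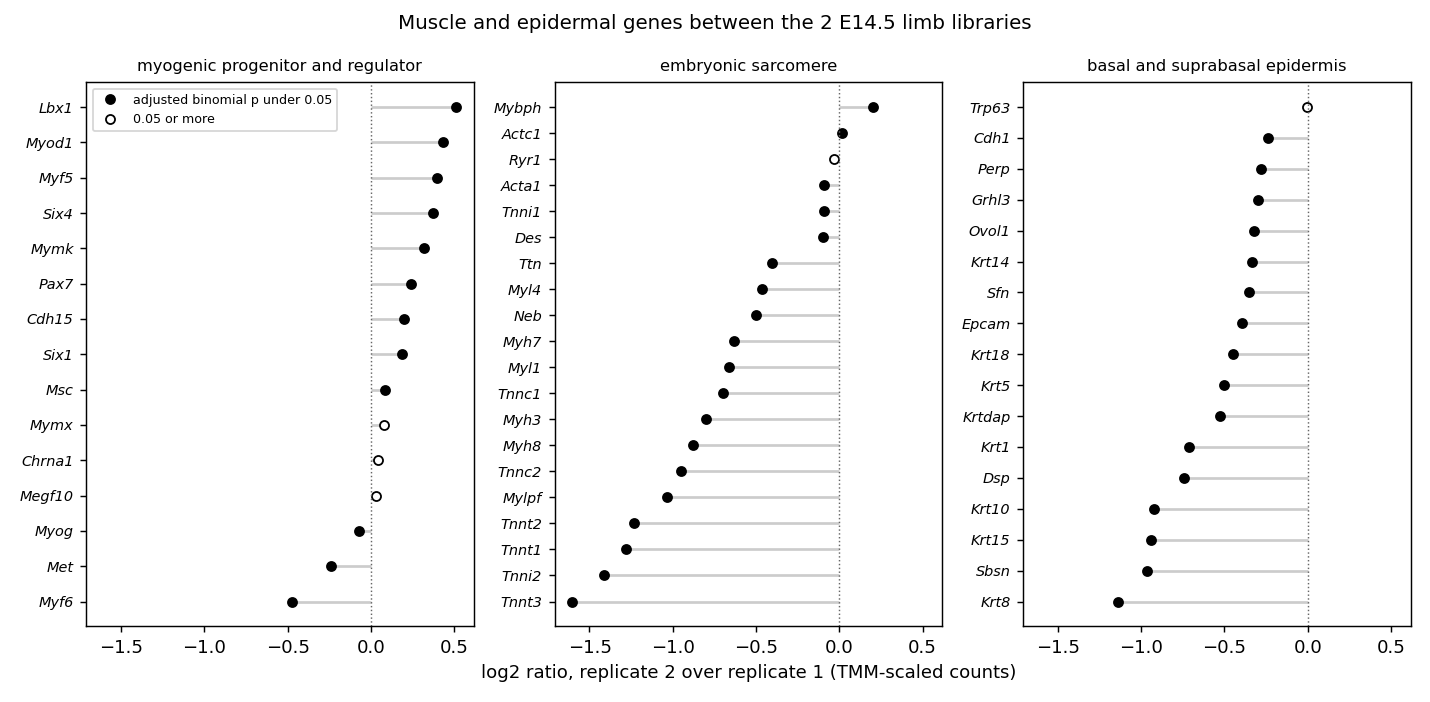
Log2 ratio of TMM-scaled counts, replicate 2 over replicate 1, for the compared members of the myogenic regulator, embryonic sarcomere and epidermal lists, filled where the adjusted binomial p was under 0.05. Sarcomere members reach -1.60 for Tnnt3 and epidermal members -1.14 for Krt8, while 9 of 15 myogenic regulators are higher in replicate 2.

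Medians of the lists that did not stand apart ran from -0.60 for adipocyte genes (4 compared, and -0.18 over the 3 members of at least 5 TPM) to 0.24 for interdigit cell death genes (10 compared, and 0.14 with the GC and length trend removed). Cornified epidermis (-0.54, 3 compared, and -0.15 for the only member of at least 5 TPM), neuron (-0.41, and -0.27 over the 4 members of at least 5 TPM), adult fast muscle (-0.27) and proliferation genes (-0.15, 14 of 18 lower and 3 higher, and -0.08 with the trend removed) lay on the lower side without standing apart. Liver (0.23), hypertrophic cartilage (0.20), macrophage (0.18) and immediate early genes (0.15) lay on the higher side. With the trend removed the last 3 had medians of 0.13, 0.12 and -0.08, so the direction of the immediate early genes was not kept. Over all lists, 365 of 465 compared members were called over all genes tested and 376 when adjusted over the list alone.

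**Figure D4:**
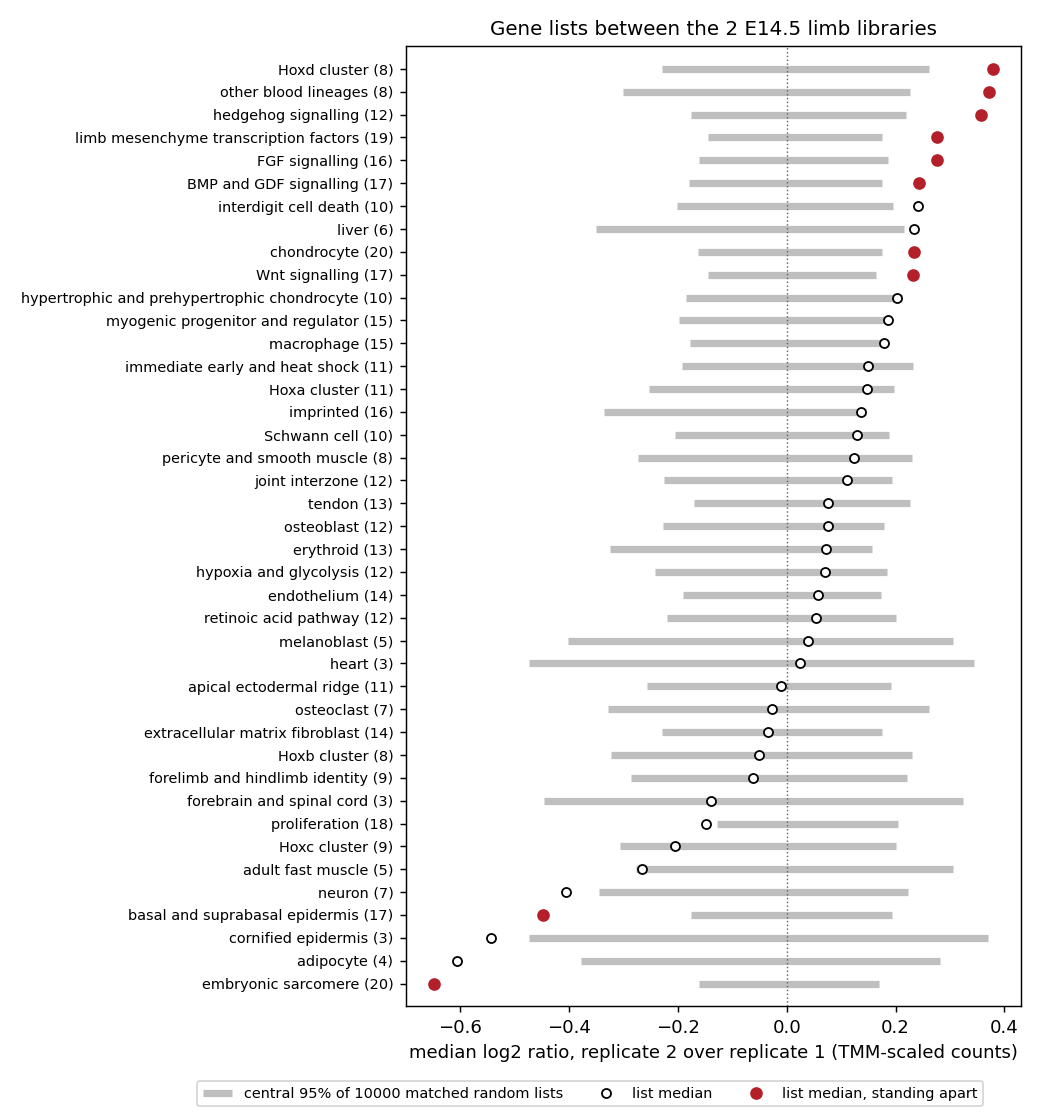
Median log2 ratio of TMM-scaled counts, replicate 2 over replicate 1, for the compared gene lists (points, number of compared members in brackets) with the central 95% of 10000 random lists matched on expression as grey bars. Lists standing apart, beyond the outermost 0.5% of random lists on either side with at least 5 members, are red, from embryonic sarcomere at -0.65 to the Hoxd cluster at 0.38; the sex-linked list at -2.75 is left out for scale, and the lung, gut, kidney and pancreas list had no member to compare.

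Sex-linked transcripts had the largest median difference of the lists, though some single genes differed more. Xist, the noncoding RNA of the inactive X chromosome (ENSMUSG00000086503.3, chromosome X, 103460366 to 103483254), was 3.86-fold higher in replicate 2 by TMM-scaled counts, and its TPM was 128 and 357 in replicates 1 and 2, a smaller ratio. The Y-linked Eif2s3y, Ddx3y, Kdm5d and Uty were 12-, 8.16-, 6.75- and 6.50-fold lower by TMM-scaled counts, with Ddx3y (ENSMUSG00000069045.7, chromosome Y, 1260771 to 1286629) falling from 17.1 to 2.30 TPM. The list's median log2 ratio was -2.75, with 1 of 5 higher and 4 lower, also when adjusted over the list alone, and the adjusted exact binomial p of each was 0 at the precision of the computation. With whole counts only, 4 members remained (median -2.89), below the 5 needed to stand apart. Both libraries held reads of Xist and of all 4 Y-linked genes, with at least 365 counts each.

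Among 6928 genes with several transcripts and at least 10 TPM in both, 6171 (89.1%) had the same leading transcript. Pkm, the pyruvate kinase gene, was led by ENSMUST00000034834.11 at 93.0% ± 1.34 of its TPM, Col2a1 by ENSMUST00000088355.7 at 72.4% ± 3.24 with ENSMUST00000023123.10 at 24.0% ± 2.82, Col11a2 by ENSMUST00000087497.6 at 75.0% ± 7.35 and Mef2c by ENSMUST00000163888.3 at 66.1% ± 3.54 (SD, n = 2). Runx2 transcript ENSMUST00000113571.5 took 40.3% ± 1.51, Fgfr1 transcript ENSMUST00000117179.4 41.2% ± 1.96, Fgfr2 transcript ENSMUST00000124096.3 29.4% ± 0.976, Meis1 transcript ENSMUST00000068264.9 38.1% ± 2.23 and Fn1 transcript ENSMUST00000055226.8 42.8% ± 7.77 of their genes (SD, n = 2). Of the 15 genes examined that have several transcripts, 6 had a different leading transcript in each library. For Tpm2 the shares were 48.5% and 26.3% for ENSMUST00000107914.5 and 14.5% and 42.5% for ENSMUST00000030184.7 in replicates 1 and 2, and for Trp63 they were 30.9% and 43.2% for ENSMUST00000040231.8 and 39.1% and 27.5% for ENSMUST00000115306.3. Tpm1 had 36.1% and 24.2% of ENSMUST00000113685.5 against 19.6% and 24.6% of ENSMUST00000113697.3, and Tnnt3 had 28.3% and 27.2% of ENSMUST00000078497.10 against 28.8% and 18.2% of ENSMUST00000105954.5. Fgfr3 was led by the protein-coding ENSMUST00000067150.9 in replicate 1 (18.9% against 16.4%) and by the retained intron transcript ENSMUST00000142860.1 in replicate 2 (24.3% against 20.3%). Vegfa was led by a retained intron transcript in each library, ENSMUST00000133605.3 at 20.6% in replicate 1 and ENSMUST00000146149.1 at 19.8% in replicate 2. Acan had 1 annotated transcript.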

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

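The phiX sequencing control had 1539774 counts in replicate 1 and 2100105 in replicate 2, above the 3 counts that a count of 0 allows. It belongs to no comparison of the report and was kept out of library sizes and tests. The difference between the libraries in phiX counts was not tested.

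The tests in this paragraph were chosen after the result was seen. Xist was higher and Y-linked transcripts were lower in replicate 2, which is consistent with more female embryos in that pool. The X-linked genes Kdm6a, Kdm5c, Eif2s3x and Ddx3x, which escape X inactivation, had a median log2 ratio of 0.37, at percentile 98.6 of matched random lists, although Ddx3x itself had -0.16. A GC or length trend between the libraries does not account for it: with that trend removed the median absolute log2 ratio of the sex-linked transcripts was 2.66, against 0.79 for 2 residual SDs. The sex of the embryos was not counted, so this explanation remains open.

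The tests in this paragraph were chosen after the result was seen. Sarcomere genes were lower in replicate 2, and with the GC and length trend removed their median log2 ratio was -0.54, at percentile 0.0 of matched random lists, so the trend alone is not the cause. A lower share of all muscle cells would lower myogenic regulators by about as much, but their mean log2 ratio was 0.14 (SD 0.27, n = 15 genes) against -0.63 (SD 0.52, n = 20 genes) for sarcomere genes. The permutation p of this difference, 2.0e-05, adds nothing to that, because the sarcomere list was taken up for being low and genes are not independent replicates. A lower share of differentiated fibres was not tested. It would lower sarcomere genes together, and 17 of 20 were lower by the binomial test. Actc1 and Acta1, however, stood at 1117 and 686 TPM in replicate 1 and 1147 and 654 TPM in replicate 2. Such a share alone would therefore not account for all members.

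The tests in this paragraph were chosen after the result was seen. Of 82 ribosomal protein genes 71 were lower in replicate 2, with a median log2 ratio of -0.47. After removal of the GC trend the median was -0.48 (percentile 0.0 of matched random lists), after removal of the length trend -0.35 (percentile 0.0), after removal of both -0.31 (percentile 0.0), and among the 12 genes with whole counts -0.40 (percentile 0.17). Neither the GC trend nor the length trend accounts for the whole difference, though both trends together account for part of it. A whole count does not exclude shared reads, and only 12 of the 82 genes had whole counts. Those genes therefore cannot decide whether reads shared with pseudogene copies played a part. The libraries also differed in the length taken off transcripts to give their effective length, a median of 199 and 226 nucleotides in replicates 1 and 2. Ratios of the deposited TPM, which use the effective length, had a median of -0.40 (percentile 0.0). Whether this difference in length lowered these genes in another way was not tested. No biological explanation was tested for this pattern.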

How the results depend on the processing

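Correlation and spread changed little, and 11299 to 15959 genes were detected, with 6 to 10 lists above the 99th percentile of random lists. At a limit of 5 TPM the detected members changed markedly for 11 of 43 lists, Hoxb falling from 8 to 1 and apical ectodermal ridge from 10 to 5. As shares of TPM in place of counts, mitochondrial genes took 6.94%, haemoglobin genes 2.23%, ribosomal protein genes 13.1% and the 10 genes with the most counts 5.67%, since TPM divides by length. The edgeR exact test with the common dispersion called 203 genes between the libraries (54 at least 2-fold higher and 149 lower in replicate 2), as it adds replicate spread to counting noise. Among genes with whole counts only, an alternative added after seeing the data, 255 were at least 2-fold higher and 539 lower; the cause was not tested. Without the low-value filter limma called 0 of 40 pairs (18 at an unadjusted p under 0.05); the cause was not tested.

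Lists standing apart numbered 11 with DESeq2 size factors, 8 with TPM ratios, 12 with members of at least 5 TPM, 9 with the GC and length trend removed and 11 with whole counts. Some lists stood apart only then: neuron genes with TPM ratios (-0.50) and whole counts (-0.41), hypertrophic cartilage (0.34) and immediate early genes (0.29) at 5 TPM, immediate early genes with whole counts (0.45, but -0.08 with the trend removed, a change of direction), and adult fast muscle (-0.34), liver (0.29) and imprinted genes (0.19) with the trend removed. Posterior mean TPM gave 30 called pairs, and 89.2% of genes with the same leading transcript. Tnnt3 transcript ENSMUST00000078497.10, the largest by mean share, moved to 26.4% of its gene; the cause was not tested.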

Other observations

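Genes of other organs differed between the libraries in a few cases, all chosen after their values were seen. The neural regulators Neurog2 and Neurod1 had 102 and 38 counts in replicate 1 and 18 and 0 in replicate 2. The liver genes Alb and Ahsg had 789 and 107 counts against 139 and 22, whereas 4 of 6 compared liver genes were higher in replicate 2 and 1 was lower (median log2 ratio 0.23, and 0.29 with the GC and length trend removed, where the list stood apart as higher). In the other direction the granulocyte genes Mpo and Elane had 120 and 17 counts in replicate 1 and 352 and 78 in replicate 2. No cause was tested for any of these.

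The proliferation list had a median log2 ratio of -0.15, and -0.08 with the GC and length trend removed, and did not stand apart. Mki67, Top2a and Tpx2, chosen after their values were seen, had log2 ratios of -0.99, -0.62 and -0.59, far beyond that median. Among adipocyte genes Fabp4 and Pparg had log2 ratios of -1.11 and -1.03 but Cebpa and Lpl only -0.14 and -0.18, and the neuron list had 6 of 7 compared members lower.

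For some genes counts and TPM gave different pictures. The tendon regulator Mkx had a log2 ratio of 0.03 in counts but 25.5 and 42.6 TPM in replicates 1 and 2. The Y-linked noncoding gene Gm29650, chosen after its values were seen, had 189 and 16 counts.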
